A study of Fundulus heteroclitus with 8 samples.

How the data were processed

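Testis RNA of adult male mummichog (Fundulus heteroclitus, a small estuarine killifish) was measured on 8 single-colour Cy3 Agilent arrays of a custom mummichog design, all on 1 slide, with 1 array per sample. Per the labels, 4 samples came from control males and 4 from males held for 21 days in water with 50 µg/L of 5α-dihydrotestosterone (DHT), an androgen that aromatase does not turn into an estrogen. The labels call the samples biological replicates taken from individuals. Males exposed to 5 µg/L are mentioned in the labels, and arrays of them were not analysed here. Groups and replicate numbers were taken from the sample titles.

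Each array carried 14850 spots, of which 536 were control spots and 14314 held 7157 probes at 2 spots each. The deposited spot intensity was the processed green signal of Agilent Feature Extraction 10.7.1.1, which had subtracted background and detrended the signal within each array, per the file headers. The deposited median spot intensity and median local background intensity were used for an alternative. Deposited flags for spots well above background, uniformity and population outliers and saturation were used as given. No spot was saturated (0 spots), and 28 of 114512 readings carried an outlier flag and were left out. The authors also deposited a table of log2 values in which every array had the same median of 7.47. Its correlation over spots with the log2 scanner signal of the same array was 0.995 to 1.00, so its scale and direction were settled by the scanner values. All 14850 sorted values were equal on the 8 arrays within 1e-06, which is what quantile normalization over all spots gives, while the tool that made the table is not given in the sources used here.

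Log2 processed signal minus the array's 75th percentile over non-control spots was the value analysed, so that a level of 0 means as bright as that percentile. The spots of a probe were averaged. A probe was tested if it was well above background on at least 4 of the 8 arrays, which kept 5989 probes, and 4599 of them were well above background on all 8. Gene names are the product names that the array design gives, many of them names of the closest protein in another organism. There were 3664 product names, and 2576 probes had none. Among the tested probes 3964 carried 1 of 3257 product names. Of 119 probes named by a sequence accession, 0 matched the reference table of 34686 mummichog genes (assembly MU-UCD_Fhet_4.1), so the names of the design were kept and no coordinates are given. The number of arrays limits the precision, and the median standard error of a log2 change was 0.45.

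DHT50 was compared with control by linear models with empirical Bayes moderation (limma 3.58.1 in R 4.3.3, lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the tested probes. On arrays simulated from the measured means and spreads, with 200 of the 5989 probes changed, this fit recovered 5.97% of the 2-fold, 47.6% of the 4-fold and 77.3% of the 8-fold changes, and 4.82% of its calls were false. The simulated noise was independent between probes. Differences between arrays shared by many probes were thus left out, and these shares may not hold for the measured arrays. Gene lists for steroid synthesis, hormone signalling, cell types and cell functions, 20 in all, were matched by product name, with the brightest probe of each name. The 18 lists with at least 5 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, again with correlations estimated from the arrays, and with fry. Differences of single values between groups were tested by exact two-sided permutation over the 70 assignments of the 8 arrays.

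Groups, lists, tests, alternatives and the rule for named genes were fixed before the data were examined. That rule names, for each direction, 12 product names past adjusted p 0.05, and where fewer passed, those with the smallest unadjusted p under 0.05. It also allows the members of the steroid and hormone lists and up to 4 members of every other list. Alternatives fixed beforehand were normexp background correction with an offset of 50, quantile and median normalization, the deposited log2 table, no filter or a stricter filter on dim probes, moderation with trend and robust, array weights, the replicate number or the slide row as a block, each slide row alone, each array left out, the 2 other list tests, and the mean of a name's probes. The mean spot signal was not used here, so normexp was run on the median spot signal. Array brightness as a covariate, the joint removal of control 1 and DHT50 2, stricter list membership and a list of interferon genes were chosen after seeing the data. The part of a list's mean change carried by brightness or slide row was its slope within groups times its gap between groups, with a 95% t interval.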

Results

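Transcript levels were measured in the testis of 8 adult male mummichog, 4 controls and 4 exposed for 21 days to 50 µg/L of DHT in the water (DHT50). Of 7157 probes, between 4742 (DHT50 2) and 6227 (control 4) were well above background on an array. The 75th percentile of log2 signal, the brightness of an array, ranged from 7.97 in DHT50 2 to 11.21 in control 1, a 9.44-fold range. Correlation of log2 values over probes was 0.820 to 0.964 between arrays of a group and 0.776 to 0.966 between arrays of different groups. The pair lowest of all was control 1 with DHT50 2.

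The series title places the exposure beside steroid production, and the comparison here asks which testis transcripts differed between DHT50 and control males. Small inducible cytokine B10 (CXCL10), a chemokine induced by interferon gamma, lay 2.35 ± 0.60 (log2 change ± SE, n = 4 per group) above control, and interferon regulatory factor 1 lay 1.92 ± 0.58 above, the latter 1.16 under normexp. ATP-binding cassette, sub-family G, member 8, part of a sterol exporter, had a change of -1.73 ± 0.32, with only 1 of 4 DHT50 arrays well above background and -0.55 under normexp. Deiodinase type I, which removes iodine from thyroid hormones, had a change of -1.51 ± 0.32. Both were below all controls on 4 of 4 DHT50 arrays. None of these passed the adjusted threshold (adjusted p = 0.685 for each), and limma called 0 of 5989 probes, the lowest adjusted p being 0.216. At an unadjusted p under 0.05 there were 282 probes, 197 higher and 85 lower, where 299 would pass by chance, and 118 of the 282 had no product name. This count was 155 without control 1, 168 without control 2, 1389 without DHT50 1 and 137 without DHT50 3. The balance of directions did not hold with the slide row as a block (182 higher and 211 lower) or in slide row 1 alone (127 and 299), and was nearly even with array weights (666 and 613) and in slide row 2 alone (166 and 152).

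The 12 names taken in the higher direction all had an adjusted p of 0.685. Among them were 2 regulators of actin assembly, Wiskott-Aldrich syndrome protein family member 2 at 1.82 ± 0.53 and Enabled protein homolog at 1.88 ± 0.57 on its brightest probe. The 2 probes of Enabled protein homolog ranged from 0.44 to 1.88, and on the brightest 3 of 4 DHT50 arrays were above every control. Hemoglobin alpha-D chain, a globin of red blood cells, had a change of 1.50 ± 0.37 and was above every control on 4 of 4 DHT50 arrays. Tumor necrosis factor receptor superfamily member 13B, a receptor of lymphocytes, was at 1.37 ± 0.41, and ectonucleoside triphosphate diphosphohydrolase 1, which degrades extracellular ATP, at 1.50 ± 0.43. Testican-3, a matrix proteoglycan, was at 1.36 ± 0.33. Cisplatin resistance-associated overexpressed protein had a change of 1.90 ± 0.48 and was well above background on 1 control and 3 DHT50 arrays. Gamma-gliadin at 1.59 ± 0.39, App1 protein at 1.53 ± 0.41 and Vegetative cell wall protein gp1 at 1.61 ± 0.41 carry names from other organisms, and the 3 probes of the last ranged from -2.15 to 1.61. With normexp 9 of the 12 changes were smaller by over 1.5 times, among them cisplatin resistance-associated overexpressed protein at 0.59, Tumor necrosis factor receptor superfamily member 13B at 0.53 and Hemoglobin alpha-D chain at 0.83.

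Of the 12 names in the lower direction, again all at adjusted p = 0.685, several are proteins that the liver secretes. Hepatocyte growth factor activator had a change of -3.68 ± 1.28, complement C3 of -2.02 ± 0.73 and ceruloplasmin, the copper carrier of plasma, of -1.84 ± 0.58. Each was highest in control 1, where hepatocyte growth factor activator stood at 4.47, while its control mean was 0.46 ± 2.99 (SD, n = 4), and without control 1 its change was -2.35. GTP-binding protein RAD was at -1.59 ± 0.51 and Krueppel-like factor 15, a transcription factor that responds to glucocorticoids, at -1.28 ± 0.46. Microsomal glutathione S-transferase 3 was at -1.28 ± 0.44, mitochondrial ribosomal protein L33 isoform a at -1.14 ± 0.39, retinol dehydrogenase 8 at -1.07 ± 0.38 and transcript expressed during hematopoiesis 2 at -0.89 ± 0.31. Glyceraldehyde-3-phosphate dehydrogenase, an enzyme of glycolysis, was at -1.41 ± 0.51 on its brightest probe, with -0.93 without control 1, and its 8 probes ranged from -1.93 to 0.33. Background limited several of these: ATP-binding cassette, sub-family G, member 8 and Krueppel-like factor 15 were each well above background on 4 control arrays and 1 DHT50 array. With normexp 7 of the 12 changes were smaller by over 1.5 times, among them GTP-binding protein RAD at -0.54, Krueppel-like factor 15 at -0.55 and complement C3 at -1.02.

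**Figure D1:**
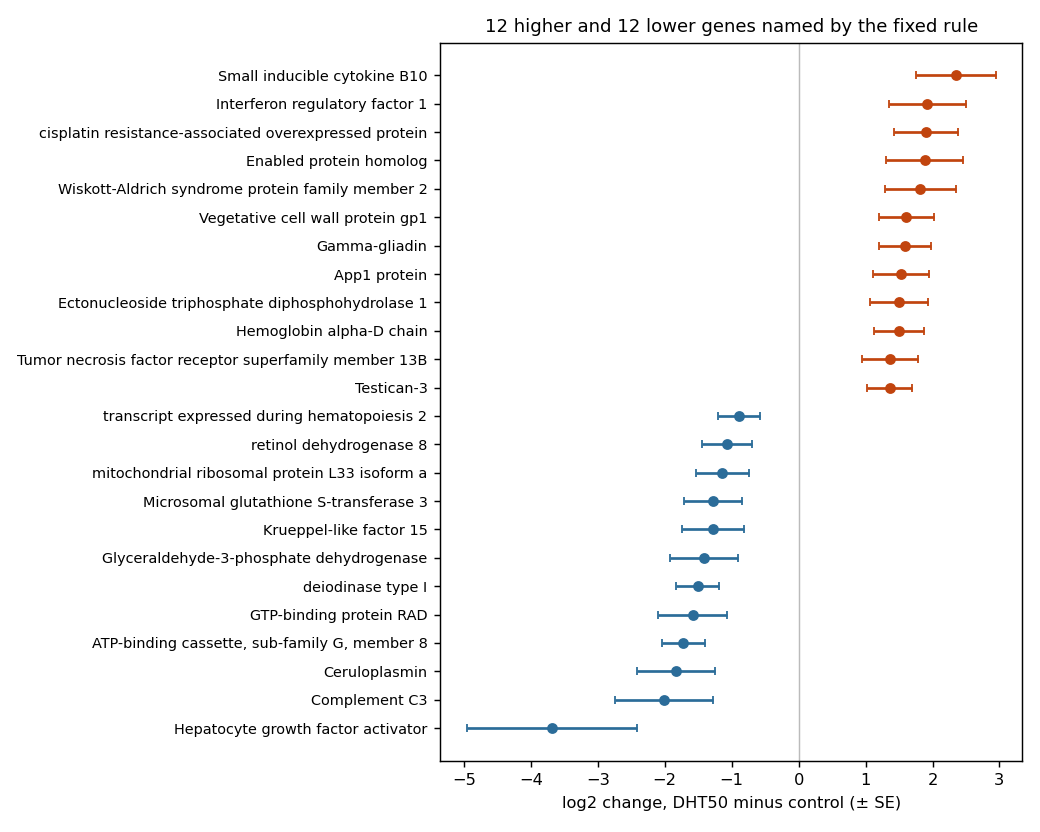
Log2 change of DHT50 against control (x axis, log2 units) for the 24 product names taken by the fixed rule (y axis); points are limma estimates and bars are ± 1 SE, with 4 arrays per group. The 12 higher names run from 1.36 for Testican-3 to 2.35 for Small inducible cytokine B10, the 12 lower from -3.68 for Hepatocyte growth factor activator to -0.89 for transcript expressed during hematopoiesis 2, and none passed the adjusted threshold.

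The list of steroid synthesis enzymes, matched by product name, was lower in 7 of 10 and higher in 3, and did not pass (mean log2 change -0.34 ± 0.25, adjusted p = 0.212). L-xylulose reductase, a carbonyl reductase of sugar metabolism, was its only member at an unadjusted p under 0.05 (-1.32 ± 0.52). Beside it the list took up Carbonyl reductase, Dehydrogenase/reductase SDR family member 4, a sterol isomerase of cholesterol synthesis and a sulfotransferase, which are not steps from cholesterol to androgens. Hydroxysteroid dehydrogenase like 2 and hydroxysteroid (17-beta) dehydrogenase 4 were also members. No cholesterol side-chain cleavage enzyme or aromatase was among the 10, so the list covers little of steroid synthesis. Estradiol 17-beta-dehydrogenase 8 was at -0.87 ± 0.40, Steroidogenic acute regulatory protein, which carries cholesterol into mitochondria, at -0.63 ± 0.57 and Cytochrome P450 17A1, which makes androgen precursors, at 0.79 ± 0.62. The change of Steroidogenic acute regulatory protein was 0.12 with the slide row as a block, and that of Cytochrome P450 17A1 was -0.61 in slide row 1 alone. With normexp these 2 changes were -0.16 and 0.36, and Steroidogenic acute regulatory protein was well above background on 4 control arrays but only 2 of 4 DHT50 arrays. No member passed over all probes or when adjusted over the list alone (0 of 10 each). Without DHT50 3 the list passed, while with the slide row as a block its mean was -0.20 ± 0.29 (adjusted p = 0.343), with -0.56 within row 1 and 0.16 within row 2. Without DHT50 1 Steroidogenic acute regulatory protein was at -0.31, and without DHT50 2 Estradiol 17-beta-dehydrogenase 8 was at -0.55 and Cytochrome P450 17A1 at 1.32, while without DHT50 4 the last was at 0.40 and Steroidogenic acute regulatory protein at -1.22.

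Hormone receptors and gonadal signals were higher in 19 of 28 genes, 2 of them at an unadjusted p under 0.05, with a mean change of 0.14 ± 0.30 (adjusted p = 0.293). By its name pattern the list also took up products that are neither, such as Telomerase-binding protein p23 and Hsc70-interacting protein. Activin receptor type I was at 1.28 ± 0.56, the alpha subunit of the pituitary gonadotropins (gonadotropin, alpha subunit) at 0.87 ± 0.38 and the inhibin alpha subunit, part of the gonadal hormone that restrains follicle stimulating hormone, at 0.89 ± 0.42. The follicle stimulating hormone receptor was at -1.02 ± 0.77, estrogen receptor alpha at 0.95 ± 0.80 and the luteinizing hormone receptor at 0.21 ± 0.47. With normexp the gonadotropin alpha subunit was at 0.45, the inhibin alpha subunit at 0.57 and the luteinizing hormone receptor at 0.08. With brightness in the fit, a choice made after seeing the data, the mean of the list turned to -0.24 ± 0.15 (adjusted p = 0.847), estrogen receptor alpha was at -0.22 and the luteinizing hormone receptor at -0.28. Without DHT50 1 the follicle stimulating hormone receptor was at -0.22 and estrogen receptor alpha at 1.77, and without DHT50 2 the latter was at 0.41, while the luteinizing hormone receptor ran from 0.0062 to 0.57 with 1 array left out. No member passed over all probes or adjusted over the list alone (0 of 28 each).

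Transcripts of ribosomal proteins and of the mitochondrial respiratory chain fell as lists with DHT50 under camera's preset correlation. Cytosolic ribosomal proteins, a list that by its name pattern also took up mitochondrial ones, were lower in 94 of 134 genes with a mean change of -0.23 ± 0.11 (adjusted p = 3.13e-04, and adjusted p = 0.669 with an estimated correlation). With 40S and 60S proteins only, a membership chosen after seeing the data, the mean was -0.13 ± 0.14 over 93 genes, smaller than for the whole list. Its camera p was 0.00420 at the preset correlation and 0.366 with an estimated one. The mean was 0.24 within slide row 1 and -0.36 within row 2, so a fall of cytosolic ribosomal transcripts as such is less certain. 60S ribosomal protein L3 was at -0.69 ± 0.29 and 28S ribosomal protein S16, mitochondrial at -1.01 ± 0.45, while 40S ribosomal protein S19 was at 1.30 ± 0.58 (0.62 with normexp). Oxidative phosphorylation genes were lower in 72 of 98, with a mean of -0.24 ± 0.11 (adjusted p = 0.00237, and adjusted p = 0.669 with an estimated correlation), among them NADH-ubiquinone oxidoreductase MNLL subunit at -0.75 ± 0.34, Ubiquinol-cytochrome c reductase complex 14 kDa protein at -0.99 ± 0.46 and ATP synthase g chain, mitochondrial at -0.79 ± 0.38, the last 2 at -0.61 and -0.51 without DHT50 2. No member of either list passed over all probes or adjusted over the list alone. The medians of the lists per array gave an exact permutation p of 0.0571 for ribosomal proteins and 0.114 for oxidative phosphorylation (n = 4 per group). With the slide row as a block the adjusted p was 0.00723 and 0.00848. Within slide row 1, which holds 1 control, the mean change was 0.06 for ribosomal proteins and -0.22 for oxidative phosphorylation, and within row 2, which holds 1 DHT50 array, -0.37 and -0.13. With brightness in the fit the adjusted p was 2.70e-06 for ribosomal proteins and 0.364 for oxidative phosphorylation.

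The red blood cell list, matched by product name, rose in DHT50 (11 of 15 higher, mean 0.43 ± 0.37, camera adjusted p = 0.0404), with adjusted p = 0.669 with an estimated correlation. Besides globins, band 3 and erythroid proteins it took up 5 products that do not mark erythrocytes, among them brain spectrins and Nuclear factor erythroid 2 related factor 2, a transcription factor of the oxidative stress response (1.32 ± 0.65). The other 10 alone, a membership chosen after seeing the data, had a mean of 0.41 ± 0.37 and did not pass (adjusted p = 0.134). Of these 10, 7 were higher and 3 lower, with globins on both sides. Hemoglobin alpha-D chain was the 1 member that passed when adjusted over the list alone (adjusted p = 0.0397), against 0 over all probes. The list lost its call without control 1 (mean 0.23, adjusted p = 0.189), without DHT50 2 (0.24, adjusted p = 0.118), without DHT50 4 (0.35, adjusted p = 0.118) or with normexp (0.16, adjusted p = 0.236). With brightness in the fit the mean was -0.04 ± 0.17 (adjusted p = 0.836), and without control 1 and DHT50 2 together 0.04 (adjusted p = 0.5004). With little change in its size, the call was also lost among probes well above background on all arrays (mean 0.41, adjusted p = 0.133) and with the mean of a name's probes (0.41, adjusted p = 0.0511). It was lost too within slide rows 1 (mean 0.95, adjusted p = 0.0773) and 2 (0.47, adjusted p = 0.0676), but not with the row as a block (0.71 ± 0.39, adjusted p = 0.00848). Its median per array followed array brightness (Pearson r = -0.95, exact permutation p = 2.23e-04, n = 8). Brightness is also what was subtracted from every value, so such a relation can arise from the scaling itself. Muscle transcripts were higher in 29 of 42 without passing (mean 0.20 ± 0.33, adjusted p = 0.163). They passed without control 4 and with the slide row as a block, where the mean was 0.47 ± 0.34 (adjusted p = 0.0177), while with brightness in the fit the mean turned to -0.18 ± 0.23 (adjusted p = 0.799).

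Liver and plasma protein transcripts were lower in 31 of 40 genes on the DHT50 arrays and fell as a list (mean -1.10 ± 0.99, camera adjusted p = 0.00887), with adjusted p = 0.669 with an estimated correlation. They were high in a single control. In control 1 the median of the list stood 3.73 above the genes' own means, against -1.43 to 0.44 on the other 7 arrays. Apolipoprotein A-I, the main protein of high-density lipoprotein, was at 6.62 in control 1 and at 1.75 on average in the other controls, and its change was -2.80 ± 1.29 on its brightest probe, with its 3 probes ranging from -2.80 to 0.47. Hemopexin, the plasma carrier of heme, had a change of -3.35 ± 1.61. Without control 1 these changes were -1.58 and -1.52. Without control 1 the mean change of the list was -0.20 (adjusted p = 0.885). The call was also lost without DHT50 1 (-0.95, adjusted p = 0.223), with brightness in the fit (-0.88 ± 1.23, adjusted p = 0.364), with array weights (-0.68, adjusted p = 0.2996) and without control 1 and DHT50 2 together (-0.49, adjusted p = 0.246). Its mean change was -3.86 within slide row 1, which holds control 1, and -0.043 within row 2.

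Immune cell transcripts split between directions, with 53 of 98 higher, 10 of them at an unadjusted p under 0.05, and 45 lower, 2 of them so. The mean change was 0.0049 ± 0.31, the median 0.09, and the list did not pass (adjusted p = 0.293). It passed as higher without control 1, without DHT50 4, without control 1 and DHT50 2 together, and with brightness in the fit (adjusted p = 2.10e-04). With the slide row as a block its direction was down and its adjusted p was 0.113. Within slide rows 1 and 2 its mean change was -0.57 and -0.20.

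Transcripts of germ cells and sperm gave no list past the threshold. Spermatid and flagellum genes were lower in 9 of 14 (mean -0.26 ± 0.17, adjusted p = 0.349) and cell cycle genes in 15 of 20 (-0.26 ± 0.25, adjusted p = 0.293), although Ribonucleoside-diphosphate reductase large subunit, which makes DNA precursors, was at 1.01 ± 0.36 (0.63 with normexp). L-xylulose reductase of the steroid list (-1.32 ± 0.52) also counted among the 14 spermatid and flagellum genes, through its other name, Sperm surface protein P34H. With the slide row as a block the cell cycle mean was -0.02 ± 0.23 (adjusted p = 0.834), with 0.0043 within row 1 and -0.05 within row 2. The spermatid and flagellum mean was -0.0064 within row 1 and -0.53 within row 2. Germ cell and somatic testis cell lists had 3 measured genes each and were not tested as lists, with means of -0.36 ± 0.18 and -0.04 ± 0.22. By name pattern the first took up DAZ-associated protein 2 and the second Wilms' tumor 1-associating protein, so these means do not measure the cell types. DEAD-box protein 4, the germ cell marker vasa, was at -0.96 ± 0.54, and at -1.46 without DHT50 1.

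None of the remaining lists passed. Lower on average were proteasome and ubiquitin (mean -0.16 ± 0.15, adjusted p = 0.134, past the threshold without DHT50 1 and with array weights), xenobiotic metabolism (-0.32 ± 0.27, adjusted p = 0.163) and heat shock proteins and chaperones (-0.13 ± 0.12, adjusted p = 0.293). With brightness in the fit the proteasome mean was -0.04 ± 0.15 (adjusted p = 0.926, and adjusted p = 0.0113 for the brightness term itself), and with the slide row as a block that of heat shock proteins was -0.01 ± 0.11 (adjusted p = 0.636). The xenobiotic list passed with normexp, without DHT50 3, with the slide row as a block (-0.46 ± 0.31, adjusted p = 0.0140) and in slide row 1 alone. Its mean was 0.0066 within slide row 2, where cholesterol synthesis and transport stood at 0.37, and within row 1 heat shock proteins stood at 0.11 and apoptosis and DNA damage at 0.16. Fatty acid and lipid metabolism (-0.27 ± 0.12, adjusted p = 0.362), apoptosis and DNA damage (-0.16 ± 0.16, adjusted p = 0.352) and cholesterol synthesis and transport (-0.07 ± 0.24, adjusted p = 0.940) were also lower on average. Egg envelope and yolk proteins, which estrogen induces in fish liver, had a mean of 0.12 ± 0.38 (adjusted p = 0.562), which turned to -0.38 ± 0.11 with brightness in the fit (adjusted p = 0.364) and was -0.09 within slide row 2. Extracellular matrix had a mean of -0.04 ± 0.22 but a median of 0.07 and a test direction of up (adjusted p = 0.523). Metallothionein, a metal-binding protein of the xenobiotic list, was at -0.995 ± 0.42, and Proteasome activator complex subunit 1 at 0.95 ± 0.31 (0.47 with normexp). In none of these lists did a member pass over all probes or adjusted over the list alone.

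**Figure D2:**
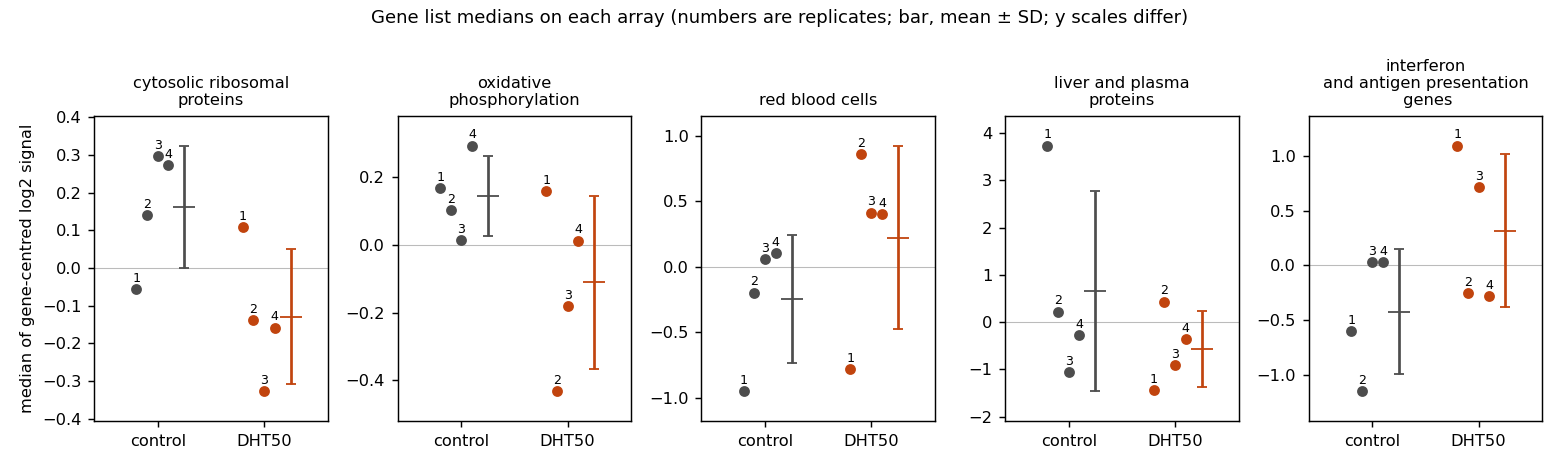
Median over each list of log2 signal centred on each gene's mean over all arrays (y axis, log2 units, scales differ between panels) in control and DHT50 testis; points are single arrays with their replicate number, and the bars to the right of them are the mean ± SD of 4 arrays. Control 1 stands at 3.73 in the liver and plasma panel, and the ribosomal medians averaged 0.16 ± 0.16 in control and -0.13 ± 0.18 in DHT50. The list at the right was chosen after seeing the data.

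The spread between arrays followed their brightness. Since brightness is also the percentile subtracted from every value, relations with it can arise from the scaling itself, which the permutation p below do not test. Brightness was 10.33 ± 0.59 (SD, n = 4) in control and 9.39 ± 1.23 in DHT50, an exact permutation p of 0.257. The strongest spike-in control, an added control RNA, ranged over 0.74 on the log2 scale, against 3.24 for brightness. The first principal component held 41.9% of the variance and the second 25.1%, and their difference between groups did not pass an exact permutation test (exact p = 0.143 and 0.657, n = 4 per group). Among 7 measures set against brightness over the 8 arrays, the first component had r = -0.92 (exact permutation p = 0.00211, adjusted 0.00738) and rho = -0.90 (exact permutation p = 0.00456, adjusted 0.0160). The red blood cell list had r = -0.95 (adjusted p = 0.00156 by exact permutation) and rho = -0.93 (exact permutation p = 0.00223, adjusted 0.0156). Oxidative phosphorylation had r = 0.86 (exact permutation p = 0.00702, adjusted 0.0123) and rho = 0.81 (exact permutation p = 0.0218, adjusted 0.0489), and muscle had r = -0.87 (exact permutation p = 0.00434, adjusted 0.0101) and rho = -0.79 (exact permutation p = 0.0279, adjusted 0.0489). Without the 2 arrays farthest from the median brightness these r were -0.93, -0.94, 0.67 and -0.79. Ribosomal proteins (r = 0.46, exact permutation p = 0.257, adjusted 0.359, and rho = 0.55, exact permutation p = 0.171, adjusted 0.239), liver and plasma proteins (r = 0.27, exact permutation p = 0.471, adjusted 0.550, and rho = -0.12, exact permutation p = 0.793, adjusted 0.840) and immune cells (r = 0.05, exact permutation p = 0.914, adjusted 0.914, and rho = 0.10, exact permutation p = 0.840, adjusted 0.840) did not pass, and without those 2 arrays their r were 0.67, -0.37 and 0.21. These correlations pool both groups and both slide rows, and none was computed within the 4 arrays of a row.

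**Figure D3:**
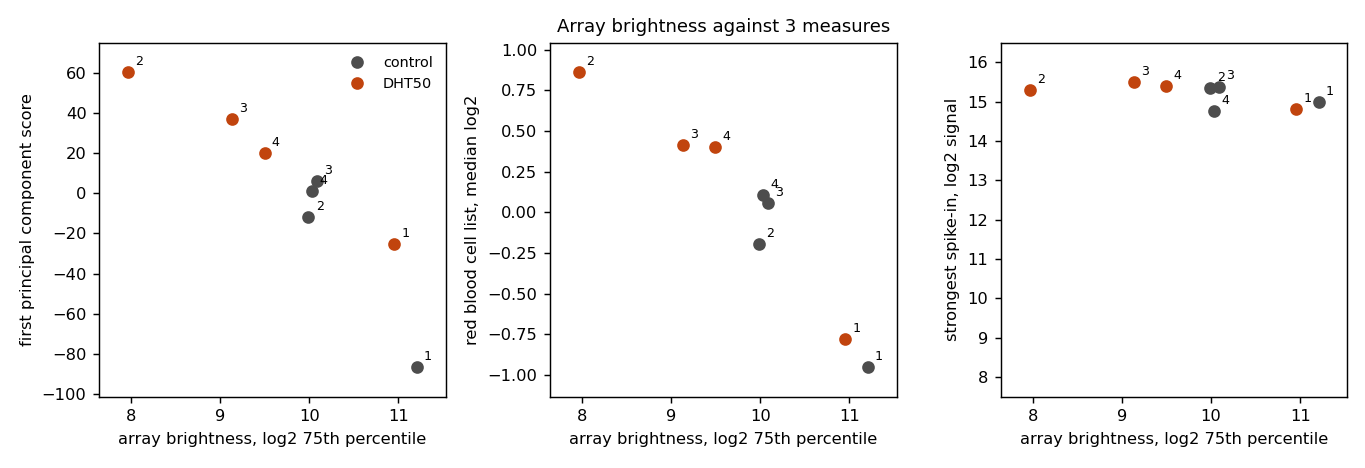
Array brightness (x axis, log2 of the 75th percentile of signal) against the first principal component score, the median of the red blood cell list (log2 units) and the strongest spike-in control (log2 signal); each point is 1 array, coloured by group and numbered by replicate. DHT50 2 is the dimmest array at 7.97 and control 1 the brightest at 11.21, while the spike-in ranged over 0.74.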

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

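The tests of liver RNA and of brightness in control 1, of brightness for the gene lists and of the spike-in range were chosen only after the result was seen, as was the interval of the part of a change that brightness or the slide row carries. Of 136 groups of 4 arrays examined for an array far from the rest, 7 had a gap over range above Dixon's critical value, where chance gives about 1 in 20, or 6.80. Control 1 stood apart in 3 of them.

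Control 1 was far brighter than the other controls (11.21 against 9.99 to 10.09, gap over range 0.920). Its deiodinase type I was higher (-0.52 against -1.34 to -1.20, gap over range 0.8293) and its mitochondrial ribosomal protein L33 isoform a lower (-2.40 against -1.30 to -1.14, gap over range 0.874). Control 4 had the highest median of spermatid and flagellum genes among controls (0.46 against -0.12 to -0.02, gap over range 0.830). DHT50 4 had the lowest median of immune cell genes in its group (-0.39 against 0.07 to 0.08, gap over range 0.993). DHT50 1 was lowest for Enabled protein homolog (-2.16 against -0.26 to -0.10, gap over range 0.926) and for the luteinizing hormone receptor (-4.73 against -3.43 to -3.19, gap over range 0.847).

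Control 1 also held transcripts of liver and plasma proteins at a median of 4.27 (log2) above the other controls, 19.3-fold, with transferrin at 7.20 against 1.38 and apolipoprotein A-I at 6.62 against 1.75. Brightness of that array is argued against, since the list stood 4.95 above the line on brightness through the other 7 arrays, whose residual SD was 0.57. The 100 products brightest in the other controls were lower in control 1 by a median of only -0.38 (SD 0.43). They were picked by signal and not for being particular to testis, so this cannot exclude another tissue in place of testis. The germ cell marker DEAD-box protein 4, a single gene, stood at 0.03 in control 1 and at -1.17 to -0.24 in the other controls. Another tissue, liver RNA carried into this sample at dissection and expression of these genes by the testis of that fish all stay open. Each could put these genes highest in control 1, so the share that were does not separate them (75% of the 40, chance giving 12.5%). Of the 40, 29 were measured on all 7 other arrays and 1 is also in another list.

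The lists that moved with DHT50 may partly follow array brightness rather than exposure. With brightness in the fit the adjusted p became 0.364 for oxidative phosphorylation (-0.24 ± 0.11 before, -0.14 ± 0.11 after) and 0.836 for red blood cells (0.43 ± 0.37 before, -0.04 ± 0.17 after), because the change itself shrank, the part that brightness carried being -0.09 (95% interval -0.23 to 0.04) and 0.47 (0.26 to 0.69). For ribosomal proteins the camera call stayed at adjusted p = 2.70e-06, and the part carried by brightness was 0.03 (-0.15 to 0.20) of a change of -0.23. Brightness thus carried none of that fall in this fit. The mean left was -0.26 ± 0.14, an SE too wide to exclude brightness as the whole source. With the slide row as a block the camera adjusted p was 0.00848 for both oxidative phosphorylation and red blood cells and 0.00723 for ribosomal proteins. Each list kept its direction, which had been set beforehand as the outcome against the row. These p rest on the preset correlation of 0.01, however, where 0.10, 0.39 and 0.15 were estimated. The parts the row carried were -0.06 (-0.22 to 0.11), -0.28 (-0.79 to 0.23, against the direction of the change) and -0.07 (-0.24 to 0.09). The means left were -0.18 ± 0.13, 0.71 ± 0.39 and -0.16 ± 0.13. These SE are too wide to exclude the row, so slide row and exposure cannot be told apart for these lists. Scanner gain or washing is argued against as the source of the brightness differences, because the strongest spike-in ranged over only 0.74 of the 3.24 that brightness did, which leaves RNA amount or labelling, or the exposure, as open and untested.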

How the results depend on the processing

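Brightness as a covariate, the removal of control 1 with DHT50 2 and stricter list membership were chosen after seeing the data, as were all alternatives of the principal components, and the causes of the differences below were not tested unless stated. No probe passed the adjusted threshold in any alternative but slide row 1 alone, which gave 106, 105 of them lower and 105 highest in control 1, the single control of that row, with 18 in the liver list. Probes at an unadjusted p under 0.05, 282 as reported with 197 higher and 85 lower, numbered 81 with normexp, 1279 with array weights, 426 in slide row 1 alone, 160 without control 1 and DHT50 2 together, and 137 (without DHT50 3) to 1389 (without DHT50 1) with 1 array left out. Lower probes outnumbered higher ones with the slide row as a block (182 higher and 211 lower) and in slide row 1 alone (127 and 299), and the balance was nearly even with array weights (666 and 613) and in slide row 2 alone (166 and 152). Same-numbered samples did not all deviate together (correlations of 0.20, 0.16, 0.38 and -0.11, and control 2 and control 4 correlated best with another number), and the replicate block gave 597 probes, 0 adjusted and the same 4 lists. Lists past the threshold, 4 as reported, numbered 2 in slide row 1 alone, 1 in slide row 2 alone, 0 with an estimated correlation, 0 with fry (lowest adjusted p 0.638), 2 with brightness in the fit, 2 without control 1 and DHT50 2, and 3 to 6 with 1 array left out. Ribosomal proteins passed in 23 of 26 alternatives (adjusted p 3.12e-08 to 0.803), oxidative phosphorylation in 20 of 26 (5.99e-04 to 0.669), liver and plasma proteins in 19 of 27 (7.37e-28 to 0.885) and red blood cells in 14 of 26. With 40S and 60S proteins only, the ribosomal mean was -0.13 ± 0.14, and the 90 oxidative phosphorylation genes without vacuolar ATPases went from -0.26 ± 0.12 to -0.16 ± 0.11 with brightness in the fit, and their unadjusted camera p from 9.61e-05 to 0.0468. The liver list's test turned to up in slide row 2 alone (mean -0.043) and without control 1 (mean -0.20, the highest with 1 array left out, the lowest being -1.62 without control 3), while its mean stayed negative. Of 979 values of 45 named genes, 971 kept direction and side of the threshold, although the side says little where none passed, and 135 moved by over 1.5 times, 99 of them to a smaller size. Among these were 24 of the 45 genes with normexp, all smaller, such as ATP-binding cassette, sub-family G, member 8 at -0.55, 19 with brightness in the fit, 23 in each slide row alone, 13 without control 1 and DHT50 2, 6 with the slide row as a block and 0 to 6 with 1 array left out. Direction turned for Steroidogenic acute regulatory protein with the slide row as a block (0.12) and in slide row 2 alone (0.98), Cytochrome P450 17A1 in slide row 1 alone (-0.61), estrogen receptor alpha with brightness in the fit (-0.22), and the luteinizing hormone receptor with brightness in the fit (-0.28) and without control 1 and DHT50 2 (-0.12). Hepatocyte growth factor activator (-8.09) and Hemopexin (-9.34) passed in slide row 1 alone. The principal component test gave an exact permutation p of 0.0571 to 0.743 in the alternatives that could pass, and without control 1 and DHT50 2 it could not go below 0.1. Signal over background limits dim genes most on DHT50 2, where 4742 probes were well above background.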

Other observations

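The interferon list and its tests, other than the count over splits, were chosen only after the result was seen, as was the interval of the part of a change that brightness or the slide row carries.

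Genes induced by interferon and genes of antigen presentation, which load peptides on class I molecules and display them to T cells, were higher in DHT50 in 31 of 35 (mean log2 change 0.67 ± 0.48, camera p = 1.66e-06 at the preset correlation). The p was 0.112 with the correlation between the genes estimated at 0.23, and 27 of the 35 are also in the immune list. Small inducible cytokine B10 at 2.35 ± 0.60, interferon regulatory factor 1 at 1.92 ± 0.58 and Proteasome activator complex subunit 1 at 0.95 ± 0.31 were examples, each with an adjusted p of 0.685. With normexp these 3 were at 2.05, 1.16 and 0.47. The list's median per array was 1.09 in DHT50 1 and 0.72 in DHT50 3, but -0.26 in DHT50 2 and -0.28 in DHT50 4, against -1.15 to 0.03 in controls (exact permutation p = 0.171, n = 4 per group).

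A response to DHT may lie behind the interferon genes, but slide row, brightness and chance stay open beside it. The camera p of 0.112 with an estimated correlation does not settle it. With brightness in the fit the camera p was 4.14e-17, and the part it carried was -0.28 (95% interval -0.96 to 0.41) of a change of 0.67. Brightness thus carried none of the rise in this fit. The mean left was 0.95 ± 0.54, an SE too wide to exclude brightness as the whole source. With the slide row as a block the p was 0.00336 at 0.54 ± 0.59, with 1.07 within row 1 and 0.0033 within row 2, and the part the row carried was 0.13 (-0.63 to 0.89), which leaves the row open. Of the 35 splits of the 8 arrays, 9 gave a p as small as the real 1.66e-06, the smallest of the others being 4.38e-15 and the split along the slide rows among the 9, so chance was not excluded. Infection or individual differences between fish were not tested.

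Chance was not excluded for the counts of unadjusted probes and of lists either. For probes at an unadjusted p under 0.05, 13 of 35 splits gave as many as the real 282, the highest being 1549. That split set control 1, control 2, control 4 and DHT50 1 against the rest and gave several times the real count. It was picked as the highest, and it kept most arrays with their own exposure group. Without DHT50 1 the real comparison gave 1389 such probes. The count of the split thus cannot tell an exposure difference not shared by DHT50 1 from another structure of the arrays. Brightness was 9.99 to 11.21 on the arrays named for that split and 7.97 to 10.09 on the rest. Whether brightness lay behind the count was not tested. For lists, 22 of 35 splits gave as many as the real 4, the highest being 9, and the split along the slide rows also gave 4. With the slide row as a block the 4 lists of the comparison still passed, beside 2 others. The real count of 0 probes past limma's adjusted threshold (282 at an unadjusted p under 0.05) is matched by every split whatever the data, so its 35 of 35, with the highest other also 0, says nothing about chance.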
